A study of Mus musculus with 6 samples.

How the data were processed

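Lenses of E19.5 mouse embryos on a mixed C57BL/6 and FVB/N background were measured on 6 arrays, 3 of wild type littermate controls and 3 of conditional Notch2 mutants. Per the labels' protocols, lenses were dissected free of surrounding tissue and snap frozen, RNA was extracted with Trizol, and oligo(dT)-primed cDNA was transcribed into biotinylated RNA. The pair of lenses of each embryo was pooled, per the series' design text, and the labels call the arrays biological replicates.

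The deposited values are on a log2 scale and were made with RMA (robust multi-array average), per the submitters' processing notes, in a version not given in the sources used here. RMA corrects background, normalises between arrays by quantiles and summarises the probes of a probe set. The base of the logarithm is not stated, and log2 is taken from RMA's usual output and from the range of the values. As deposited, each probe set's median over the 6 arrays was 0 to within 5e-07, so the values had been centred per probe set, in a step that no source used here describes. Centring leaves differences between arrays as they were and removes the level, so no expression level, detection call or background comparison was possible. Array medians lay between -0.02 and 0.02, and array standard deviations were 0.226, 0.223 and 0.384 in wild type 1, 2 and 3 and 0.267, 0.332 and 0.273 in mutant 1, 2 and 3.

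Probe sets were named through the platform annotation given with the data: of the 45037 that are not controls, 34945 had 1 gene symbol, 932 several and 9160 none, and none was named from a probe set with several. Entrez identifiers of 34741 probe sets matched the RefSeq table of assembly GRCm38.p6, and no symbol changed. The sources used here name no genome build, so the table served only for names and for which genes lie near Notch2, and no coordinate is printed. In all 18193 genes had a probe set.

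The main test was limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no covariate) on the deposited log2 values of all 6 arrays, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. The prior had 5.07 degrees of freedom beside 4 residual ones. Simulated arrays had independent noise, equal on all arrays, with each probe set's spread drawn from limma's fitted prior. There limma called 33 of 100 probe sets changed by 1 on the log2 scale and 98 of 100 changed by 2. It also called 5 of 44837 unchanged ones, among the 45037 probe sets. The real arrays differed in their spread, so these counts are not an error rate for them.

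There were 20 gene lists and 8 cell type marker lists, fixed from general knowledge before the data were examined, as were the tests and the rule for named genes. They were tested with limma's camera at a preset correlation of 0.01 on 1 probe set per gene, adjusted over the 28 lists together, with camera at an estimated correlation and fry as alternatives. No list kept its call with an estimated correlation. In simulated arrays of 18193 independent genes with 1 list of 28 shifted by 0.5, that list passed and 0 others did. Counts of members that rose or fell refer to that 1 probe set per gene, adjusted over all probe sets and adjusted over the list alone. The plan took the probe set with the highest mean of a gene. Centred values hold no mean, so the probe set with the largest standard deviation over all 6 arrays was used, a choice made after seeing the data and without regard to genotype. It favours large changes in either direction.

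The rule named Notch2, the members of both Notch lists that pass, and Hes1, Hes5, Hey1 and Jag1. It also named the 10 largest rises and 10 largest falls among genes with an adjusted p below 0.05 and no overlap between the groups, with 1 probe set per gene and without RIKEN clones and predicted genes (88 and 44 genes met this), then Cdkn1a, Ccnd2, Trp63 and Cdh1, and up to 4 members of each list with the smallest p. Other list members are named where they passed adjusted over the list alone, and were chosen after their values were seen. Exact permutation tests compared control probe sets between groups.

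Alternatives were a repeated quantile normalisation, array medians subtracted, array weights, no probe sets of the _x_at and _s_at kinds, the replicate number as a block, each array left out in turn, other set tests, and other windows around Notch2. Chosen after seeing the data were the hybridization control split as a block, the retinal list's mean per array as a covariate, the robust variance, the probe sets more variable than the median, 1 probe set per gene by standard deviation, and leaving out retinal marker genes. The planned filter on dim probe sets and the variance trend need mean levels and were not run. A covariate that differs between all mutant and all wild type arrays, as the retinal mean does, leaves little information on genotype itself.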

Results

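Gene expression was measured in mouse ocular lenses at E19.5, shortly before birth, on oligonucleotide arrays. The wild type group held 3 littermate controls without ablation of Notch2, and the mutant group held 3 embryos in which Notch2, a receptor of the Notch signalling pathway, had been removed conditionally in the lens. Each array carried RNA from the pooled pair of lenses of 1 embryo, so the 6 arrays were biological replicates. The comparison asked which transcripts differ when Notch2 is missing from the lens. The table held 45101 probe sets, of which 64 were controls of the array maker and 45037 were tested. Each probe set was centred on its median over the 6 arrays, so the values give differences between arrays and no absolute level, and the number of arrays limits the precision. Unless stated otherwise, changes are log2 differences, mutant minus wild type, with their standard error (SE) and limma's adjusted p, and n = 3 per group.

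The targeted gene gave no settled change. Of the 2 Notch2 probe sets, the one with the larger spread differed by 0.49 (SE 0.45, adjusted p = 0.752), with values of -0.37, -0.41 and 0.43 in wild type 1, 2 and 3 and of -0.65, 1.39 and 0.37 in mutant 1, 2 and 3. The other differed by -0.42 (SE 0.21, adjusted p = 0.514), with values of 0.44, 0.08 and -0.08 against 0.10, -0.56 and -0.36. Neither probe set separated the groups. Which exons are removed, and whether either probe set lies in them, is not given in the sources used here, so these values do not check the genotypes.

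Among the transcripts that rose most in mutant lenses were Hspb1, a small heat shock protein (6.80-fold, adjusted p = 0.00101), Cdkn1a, an inhibitor of cyclin-dependent kinases (6.48-fold, adjusted p = 0.0157), and Hmox1, the inducible heme oxygenase (4.03-fold, adjusted p = 0.00334). The neurogenic transcription factors Otx2, Neurod4 and Neurog2 rose by 4.96-fold, 4.86-fold and 4.82-fold. The largest falls included Rcan2, a regulator of calcineurin (6.06-fold lower, adjusted p = 0.0277), Dnase2b, the nuclease that degrades DNA in lens fibre nuclei (5.53-fold lower, adjusted p = 0.00219), and Cdh1, the epithelial cadherin (4.14-fold lower, adjusted p = 0.0157). Cdkn1a and Cdh1 are known from the study's own published account, so their direction here is not independent evidence.

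In all, 211 probe sets passed, 132 higher and 79 lower in mutant lenses, and 190 of them changed at least 2-fold. They named 166 genes, 108 higher and 58 lower, while 23 probe sets had no single gene symbol. The smallest change that passed was 0.85 and the median size was 1.31. At an unadjusted p under 0.05 there were 5214 probe sets, against 2252 expected by chance. The groups did not overlap in 8028 probe sets, or 17.8%, against 10% by chance, and all 211 that passed were among them. With 1 probe set taken per gene, the one with the largest standard deviation over all arrays, the 10 largest rises included Hspb1, which went from -1.33 ± 0.09 in wild type to 1.44 ± 0.22 in mutants (SD, n = 3), and Hmox1, from -0.95 ± 0.02 to 1.06 ± 0.19. Sdk2, an adhesion molecule, rose by 2.36 (SE 0.18), Crym by 2.09 (SE 0.22) and Isl1 by 2.04 (SE 0.32). Thrsp rose by 2.36 (SE 0.31), although 1 of its 3 probe sets went the other way at -0.05. Nefl and Ina, neurofilament genes, passed only by probe sets other than the one taken (2.55, SE 0.41, and 2.11, SE 0.30). Of the 10 largest falls by the same rule, Dnase2b went from 1.26 ± 0.22 to -1.21 ± 0.15 and Cdh1 from 0.96 ± 0.16 to -1.09 ± 0.40. Thbs1, which encodes thrombospondin, changed by -2.32 (SE 0.21), Scn11a by -2.14 (SE 0.20), Col4a4 by -2.08 (SE 0.18) with all 3 of its probe sets passing, and Pdgfra by -1.94 (SE 0.30). Avp changed by -1.75 (SE 0.21), Olfml3 by -1.66 (SE 0.16) and Car8 by -1.89 (SE 0.22), while another Car8 probe set read 0.15. Ccnd2 and Trp63, also known from the study's account, differed by 0.29 (SE 0.31, adjusted p = 0.791) and 0.12 (SE 0.19, adjusted p = 0.866) and did not pass. All 7 Ccnd2 probe sets read above 0, up to 0.59 (SE 0.18, adjusted p = 0.224), and none passed. Of 4 Trp63 probe sets 2 went the other way. The calls rested on each array: 8 probe sets passed without wild type 1, 155 without wild type 2 (31 of them lower in mutants), 49 without wild type 3, 12 without mutant 1, 7 without mutant 2 and 91 without mutant 3, and of the 211 these held 8, 87, 41, 10, 7 and 59. The 4 genes Hspb1, Sdk2, Hmox1 and Dnase2b passed each time among the 20 with the largest changes. With each array's mean over the retinal marker genes described next as a covariate, limma called 0 probe sets, with 1334 at an unadjusted p under 0.05, and 210 of the 211 kept their sign.

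**Figure D1:**
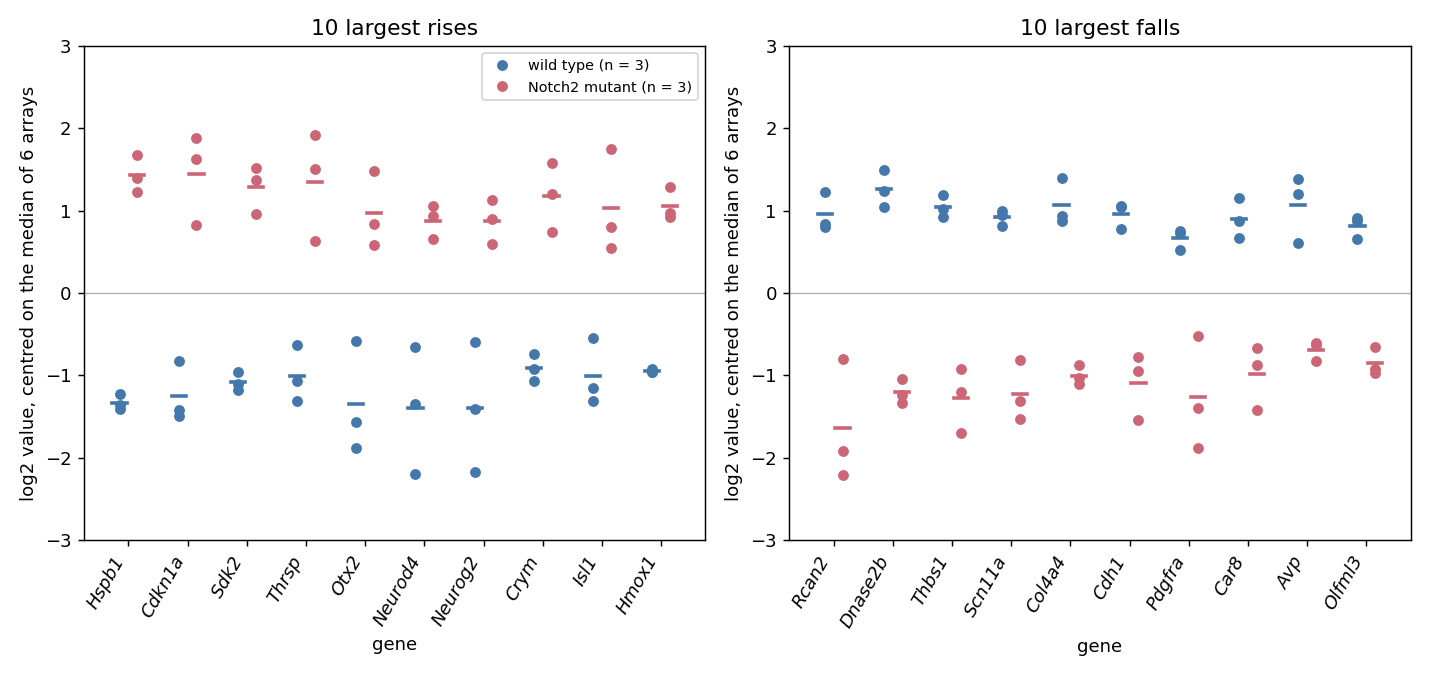
Centred log2 values of the 10 genes with the largest rises and the 10 with the largest falls, among genes that passed by the 1 probe set taken per gene. Points are single arrays (3 wild type, 3 mutant) and bars are group means. Hspb1 goes from a mean of -1.33 in wild type to 1.44 in mutants and Dnase2b from 1.26 to -1.21, and that the groups lie on opposite sides of 0 follows from the choice of genes and the centring.

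Transcripts of retinal neurons and their progenitors formed the group that moved most. Of 25 measured members of this marker list, 8 rose over all probe sets and none fell, and 21 rose and 0 fell when adjusted over the list alone. The 8 were Atoh7 (1.85, SE 0.23), which specifies retinal ganglion cells, Lhx2 (1.19), Neurod4 (2.28), Otx2 (2.31), Tubb3 (1.94), the neuronal tubulin, Isl1 (2.04), Syt1 (1.70, though another probe set read -0.29) and Elavl3 (1.27). The mean change was 1.47, with an adjusted p of 1.49e-22 in camera, limma's set test, at its preset correlation and an adjusted p = 0.279 with an estimated correlation. Per array, the list mean was -0.86, -0.35 and -1.12 in wild type 1, 2 and 3 and 0.63, 1.08 and 0.37 in mutant 1, 2 and 3. None of these genes belongs to another of the lists.

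Cell cycle genes were higher in the same arrays. Of 37 measured genes of S, G2 and M phase, 35 had a positive difference. Only Rrm2, a subunit of ribonucleotide reductase, rose over all probe sets (1.24, SE 0.20, adjusted p = 0.0422), and 28 rose and 0 fell when adjusted over the list alone, with Mcm6 at 1.23, Mki67 at 1.03 and Ccna2 at 0.99. The list's mean change was 0.69 (camera adjusted p = 4.60e-21, and adjusted p = 0.338 with an estimated correlation), and its array means of -0.45, -0.13 and -0.59 against 0.36, 0.38 and 0.16 were lowest and highest in the arrays where the retinal list was, wild type 3 and mutant 2. With the retinal mean as a covariate the shift was 0.03 (SE 0.19). Except for the crystallins, this covariate widened the SE of every list's shift, for example to 0.46 for p53 targets and 0.18 for fibre genes. Shifts given with it below are therefore imprecise. Among 24 measured G1 cyclins and cell cycle inhibitors, Cdkn1a rose over all probe sets, and adjusted over the list alone 7 rose, including Ccnd1 (1.41) and Gas1 (0.83), and Btg1 fell (-1.11). Their mean change was 0.37 (camera adjusted p = 2.72e-04, and adjusted p = 0.338 with an estimated correlation) and -0.10 with the retinal covariate. In the list of p53 targets and apoptosis genes, Cdkn1a, which the G1 list also holds, and Trp53inp1 (1.34, SE 0.21) rose among 24 measured. When adjusted over the list alone 8 rose, among them Eda2r (1.47), Pmaip1 (1.14) and Ccng1 (0.89), and Plk2 fell (-0.88, though a second probe set read 0.23). The mean change was 0.37 (camera adjusted p = 0.00594, and adjusted p = 0.494 with an estimated correlation), but 0.23 with an adjusted p of 0.177 without mutant 1, and 0.11 with the retinal covariate.

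Notch target genes did not pass as lower in the dissected lenses, and the arrays do not tell which cells the transcripts came from. Of 15 measured, Hes6 rose over all probe sets (1.29, SE 0.21, adjusted p = 0.0469). Adjusted over the list alone 5 rose and 0 fell, namely Hes6, Id3 (0.88), Hes1 (0.79, adjusted p = 0.0622 over all probe sets), Sox9 (1.01) and Dtx1 (0.90). Hes6 is itself a neurogenic factor that opposes Hes1. Hes5 (0.29, adjusted p = 0.631) and Hey1 (-0.21, adjusted p = 0.685) did not pass. The mean change was 0.35 (camera adjusted p = 0.00107, and adjusted p = 0.338 with an estimated correlation), and 0.05 with the retinal covariate. Among 28 receptors, ligands and modifiers of the pathway none passed over all probe sets, and adjusted over the list alone 5 rose: Dll3 (1.00), Dll1 (0.78), Dtx4 (1.05), Fbxw7 (0.74) and Rbpj (0.64). Jag1 was at -0.03 (adjusted p = 0.975), and the list as a whole had a mean change of 0.12 (camera adjusted p = 0.249).

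Genes of lens fibre structure and denucleation were lower in mutant lenses, with exceptions among the heat shock genes. Of 29 measured members, Dnase2b (-2.47) and Maf (-1.32, SE 0.20), a transcription factor of fibre differentiation, fell, and Hspb1 (2.77) and Dnajb1 (0.92, SE 0.14) rose. There were 13 falls and 2 rises adjusted over the list alone. The 13 included Clic5 (-1.53), the fibre gap junction gene Gja3 (-0.91), the membrane protein genes Lim2 (-0.82) and Mip (-0.59), and Tdrd7 (-0.80). The mean change was -0.42 (camera adjusted p = 1.11e-06, and adjusted p = 0.338 with an estimated correlation), and -0.14 with the retinal covariate. The crystallins, the bulk proteins of the lens, did not pass singly or together: 14 were measured, their mean change was -0.09 (camera adjusted p = 0.459), and the smallest p belonged to Crybb2 (-0.46, SE 0.18, adjusted p = 0.365).

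Among 30 measured genes of the lens epithelium, Cdh1 (-2.05) and Pdgfra (-1.94) fell and Dapl1 rose (1.04, SE 0.16). With p adjusted over the list alone 12 fell, among them Sfrp1 (-1.43), Tfap2a (-0.88), Foxe3 (-0.86) and Pitx3 (-0.80), and 3 rose, Dapl1, Meis1 (0.94, though another probe set read -0.41) and Mab21l2 (0.57). The mean change of -0.27 passed narrowly (camera adjusted p = 0.0377, and adjusted p = 0.539 with an estimated correlation). It did not pass without wild type 1 (-0.21, adjusted p = 0.126), wild type 2 (-0.26, adjusted p = 0.0609), mutant 2 (-0.23, adjusted p = 0.050, just above the threshold) or mutant 3 (-0.25, adjusted p = 0.116), and was -0.34 with the retinal covariate (adjusted p = 0.172). In the capsule and basement membrane list of 25 measured genes, the collagen IV chains Col4a4 (-2.08) and Col4a3 (-1.17, SE 0.20) fell. Adjusted over the list alone 7 fell, including Lama1 (-1.10), Lamb1 (-1.13), Nid1 (-0.73) and Sparc (-0.51), and Agrn rose (0.57). The mean change was -0.34 (camera adjusted p = 0.00116, and adjusted p = 0.279 with an estimated correlation), and -0.28 with the retinal covariate (adjusted p = 0.175).

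Heat shock and oxidative stress genes were higher as a group. Of 21 measured, Hmox1 (2.01, SE 0.16), the chaperone gene Hspb8 (1.35, SE 0.17) and the co-chaperone gene Dnajb4 (0.96, SE 0.16) rose. A Dnajb4 probe set other than the one tested for the list read -0.43. Adjusted over the list alone 5 rose, with Gsta4 (0.64) and Hsph1 (0.68), and Gstm1 fell (-1.36), which also passed over all probe sets by another probe set (-1.40, SE 0.24). The mean change was 0.32 (camera adjusted p = 4.07e-04, and adjusted p = 0.338 with an estimated correlation), and still 0.32 with the retinal covariate, where the list no longer passed (adjusted p = 0.172). The list of unfolded protein and integrated stress response genes (26 measured, mean change 0.06, camera adjusted p = 0.448) had no member that passed.

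In the signalling lists single genes stood out. Fgf12 rose by 1.95 (SE 0.15, adjusted p = 0.00334) with all 3 of its probe sets. Fgf12 was counted in the fixed FGF receptor and ERK list, which does not show that it acts through these receptors. Among the 26 measured genes of that list, adjusted over the list alone, 4 rose and Spry1 fell (-0.61). The 4 were Fgf12, the ERK phosphatases Dusp6 (0.97) and Dusp4 (1.22), and Il17rd (0.71). The list's mean of 0.24 passed in camera (adjusted p = 0.0398, and adjusted p = 0.453 with an estimated correlation) but not without wild type 3 (0.16, adjusted p = 0.20), mutant 1 (0.16, adjusted p = 0.415) or mutant 2 (0.24, adjusted p = 0.050, just above the threshold), and it was -0.16 with the retinal covariate. Of 39 Wnt pathway genes, the receptor gene Fzd5 (1.38, SE 0.19) and the secreted antagonist gene Sfrp2 (1.55, SE 0.24) rose, although another Fzd5 probe set read -0.11. Adjusted over the list alone 3 rose, with Nkd2 (0.76), and Wnt7b fell (-0.82), and the list's mean was 0.05 with a median of -0.04 (camera adjusted p = 0.711). By the probe set taken, none of 33 BMP and TGF-beta pathway genes passed over all probe sets (mean 0.12, camera adjusted p = 0.128, but 0.18 and 0.0169 with the split of the arrays by hybridization controls as a block). Ltbp1 passed by another probe set (1.08, SE 0.17). Adjusted over the list alone Bambi rose (0.72) and Inhbb fell (-1.38), though a second Inhbb probe set read 0.27. Of 24 mesenchymal transition and fibrosis genes Cdh11 rose (1.26, SE 0.22), and Mmp2 passed by a probe set other than the one taken (0.90, SE 0.14). Adjusted over the list alone 6 rose, including Acta2 (0.88) and Tgfbi (1.03, though another probe set read -0.13), and Tpm2 fell (-1.09), with a list mean of 0.17 (camera adjusted p = 0.0808) that passed without wild type 2 (0.25, adjusted p = 0.0175).

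Markers of other cell types separated into those that moved and those that did not. Of 22 macrophage and leukocyte markers none passed over all probe sets, but 9 rose and 0 fell adjusted over the list alone, among them Ctss (1.51), the complement genes C1qb (1.53) and C1qc (1.29), and Csf1r (1.39). Their mean change was 0.70 (camera adjusted p = 3.33e-07, and adjusted p = 0.338 with an estimated correlation), -0.24 with the retinal covariate, and wild type 2 (0.07) lay above mutant 1 (0.00). Of 11 glial and Schwann cell markers Slc1a3 rose (1.36, SE 0.22), and adjusted over the list alone 5 rose and 0 fell, with Fabp7 at 1.87. Their mean change was 0.47 (camera adjusted p = 0.0101, and adjusted p = 0.338 with an estimated correlation), and -0.03 with the retinal covariate. Of 19 periocular mesenchyme and fibroblast markers Col6a1 rose (1.15, SE 0.18), over all probe sets and adjusted over the list alone, and the list had a mean of 0.14 and a median of -0.03 (camera adjusted p = 0.155). The 20 endothelial markers had a mean change of -0.02 (camera adjusted p = 0.935), which was 0.25 (adjusted p = 0.0110) without wild type 2 and -0.22 (adjusted p = 0.0390) without wild type 3. No member passed in the lists of 15 pigmented epithelium and melanocyte markers (mean 0.0045, median -0.03, adjusted p = 0.935), 12 erythroid genes (mean 0.05, median -0.0040, adjusted p = 0.760) and 15 skeletal muscle genes (mean -0.05, adjusted p = 0.760), over all probe sets or adjusted over the list alone.

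The remaining lists did not pass as groups. The 42 measured genes of surface and stratified epithelium, which include Trp63, had a mean change of -0.05 (camera adjusted p = 0.708) with no member passing either way. Hypoxia and glycolysis genes (26 measured, mean -0.12, adjusted p = 0.298) held Pfkp, which rose (1.03, though another probe set read -0.40), and Bnip3, which fell (-0.91), adjusted over the list alone. Ndrg1 fell by a probe set other than the one taken (-0.95, SE 0.15). Of 24 interferon response genes (mean -0.09, adjusted p = 0.708), Rsad2 fell by 2.07 adjusted over the list alone (adjusted p = 0.0601 over all probe sets). Sterol synthesis genes (18 measured, mean -0.09, adjusted p = 0.467) and ribosomal protein genes (26 measured, mean -0.12, adjusted p = 0.302) held no member that passed, over all probe sets or adjusted over the list alone.

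**Figure D2:**
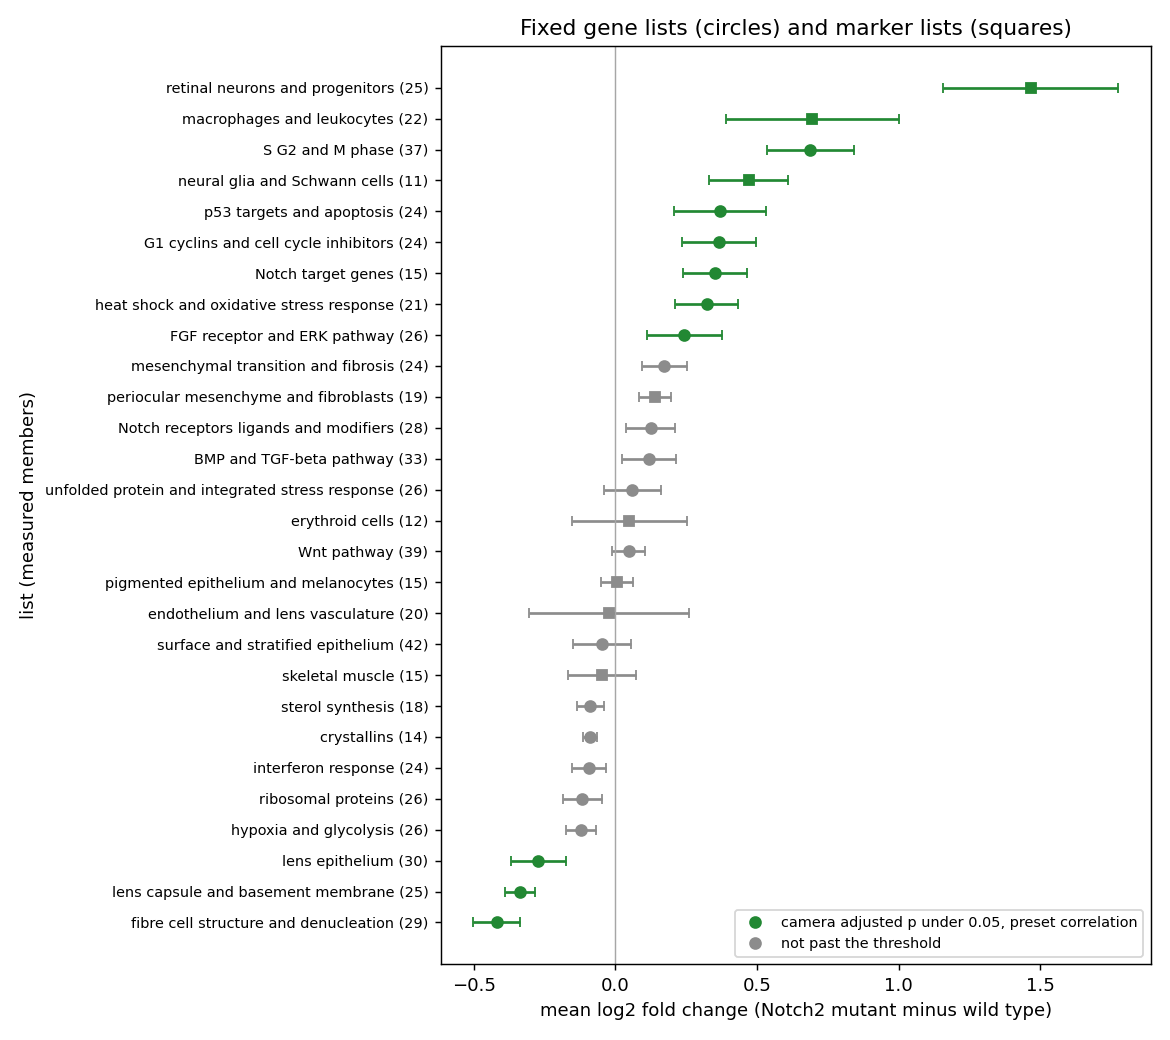
Mean log2 change of the measured members of the 28 lists, mutant minus wild type, with the number measured in brackets. Circles are gene lists, squares are cell type marker lists, bars are the SE of the difference between the 3 mutant and 3 wild type array means, and green marks camera adjusted p under 0.05 at the preset correlation. The retinal list lies furthest right at 1.47 and the fibre list furthest left at -0.42.

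The arrays also differed in their controls. Hybridization control transcripts, which are added to the sample before it goes on the array, were low on wild type 1 (-1.14), wild type 2 (-1.69) and mutant 1 (-1.72) and high on wild type 3 (1.14), mutant 2 (1.72) and mutant 3 (1.24), over 14 probe sets. Their mean was -0.56 ± 1.5 in wild type and 0.41 ± 1.9 in mutants (SD, n = 3, exact permutation test, two-sided, p = 0.6). The 3' to 5' difference was -0.05 ± 0.11 against 0.0056 ± 0.07 for Gapdh (p = 0.6, same exact test) and -0.10 ± 0.12 against 0.03 ± 0.09 for beta-actin (p = 0.2, same exact test), and the 18S probe set was at -0.16 ± 0.45 against 0.04 ± 0.59 (p = 0.9, same exact test). With 3 against 3 arrays this test allows no p below 0.1, so these p-values do not show that the groups were alike. The first principal component held 38.7% of the variance and separated the genotypes, with wild type at -14.4, -1.52 and -70.3 and mutants at 41.6, 36.1 and 8.50. The second held 28.2% and separated the arrays by their hybridization controls. Within the low and the high arrays the retinal list differed by 1.23 and 1.84, the S, G2 and M phase list by 0.65 and 0.86, the fibre list by -0.41 and -0.40, the capsule list by -0.38 and -0.26, the epithelium list by -0.22 and -0.19, the heat shock list by 0.43 and 0.36, and the Notch target list by 0.42 and 0.41. Hspb1 differed by 2.97 and 2.72, Cdkn1a by 3.05 and 2.65, Dnase2b by -2.32 and -2.53, and Cdh1 by -1.83 and -2.02. In these single genes, and in the array means of the lists just named, the groups do not overlap. The direction within each part was therefore fixed in advance for both, and only the sizes carry information. Macrophage markers differed by 0.27 in the low arrays and 1.21 in the high ones. With this split as a block 790 probe sets passed, 594 of them higher in mutants, including all 211, and the lens epithelium list no longer did (-0.21, adjusted p = 0.223). The embryos' sex is not given in the sources used here. In wild type 2 and mutant 3 Xist was high (7.19 and 7.21) and the Y-linked gene Eif2s3y low (-5.91 and -5.95), 1 array in each group.

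**Figure D3:**
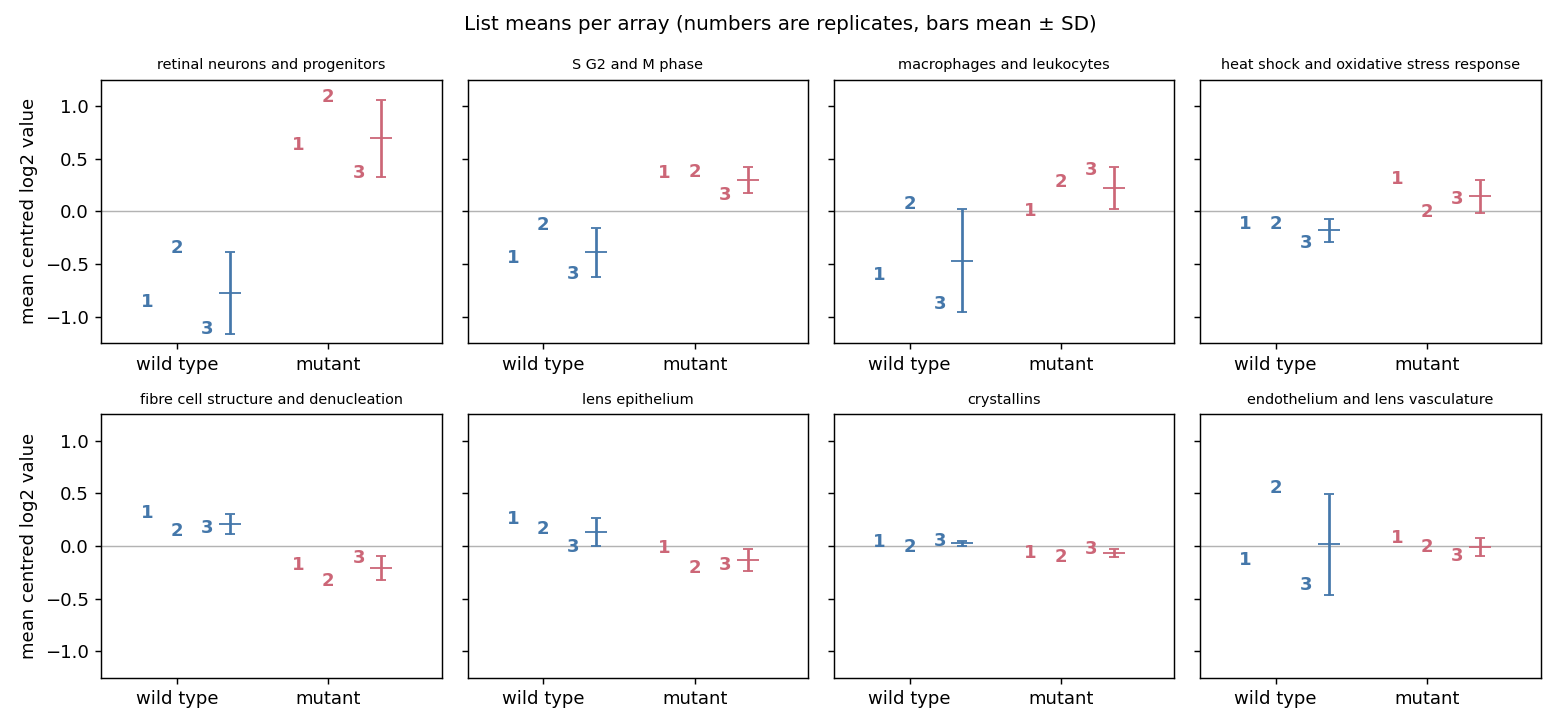
Mean centred log2 value of 8 lists on each array. Digits mark replicates 1 to 3 of wild type and mutant, and bars give the group mean ± SD (n = 3). The retinal list spans -1.12 to -0.35 in wild type and 0.37 to 1.08 in mutants, while the crystallins stay between -0.10 and 0.04.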

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

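The number of probe sets that passed depended on the setting and on single arrays, and 3 arrays per group limit it. In all 211 the groups did not overlap, so leaving out an array cannot turn their direction, and kept signs say nothing there. The planned filter on dim probe sets and the variance trend were not run because centred values hold no level. Counts not named under an alternative stayed within 1.5 times the main count there, and lists not named stayed on their side of the threshold. Over the single named genes and all alternatives together, 1956 values either passed in both settings with the same sign or passed in neither. A further 213 no longer passed, 119 newly passed and 4 changed sign. A change of sign is counted only where a value passed under either setting. Genes and lists that passed under neither may have changed sign unmentioned, as the crystallin list did with the retinal covariate (0.03). Except where the construction of an alternative is named, the cause was not tested.

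Quantile normalisation repeated on the values gave 584 probe sets (408 higher, 176 lower, 398 at least 2-fold, 210 of the 211 among them), and the FGF receptor and ERK list no longer passed (0.20). Array weights gave 889 (516 higher, 373 lower, 456 at least 2-fold, with all 211), and the p53 list (0.30) and the FGF list (0.18) no longer passed. Without _x_at and _s_at probe sets the lens epithelium list no longer passed (-0.27). The 3 further alternatives, array medians subtracted (203), robust variance (208) and 1 probe set per gene (219), stayed near the main count.

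Replicate numbers are shared by both groups, but no label ties a number to a litter or day. Deviations of arrays with the same number correlated by 0.33, -0.14 and 0.26, which neither shows nor excludes that the numbers pair the arrays. Wild type 1 and wild type 3 correlated best with their own number and wild type 2 with mutant 1 (0.30). Every wild type and mutant pair on the same side of the hybridization control split correlated positively, and every pair across it negatively. The matches of number therefore cannot be told apart from that split. With the replicate block 530 probe sets passed (385 higher, 145 lower, 425 at least 2-fold, 208 of the 211 among them), with 2 residual degrees of freedom.

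Chosen after seeing the data, the hybridization control split as a block gave 790 (594 higher, 196 lower, 470 at least 2-fold, with all 211), with the lens epithelium list no longer passing (-0.21) and the BMP and TGF-beta list passing (0.18). The probe sets more variable than the median gave 738 (514 higher, 224 lower, 591 at least 2-fold, 202 of the 211 among them). Without retinal marker genes 186 passed.

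With the retinal mean as a covariate 0 probe sets passed (0 higher, 0 lower, 0 at least 2-fold), with 1334 at an unadjusted p under 0.05. The lists of Notch targets (0.050), fibre genes (-0.14), lens epithelium (-0.34), S, G2 and M phase (0.034), p53 targets (0.11), capsule (-0.28) and heat shock (0.32) no longer passed. Those of G1 genes (-0.10, SE 0.25), the FGF pathway (-0.16, SE 0.30), macrophages (-0.24, SE 0.69) and glia (-0.029, SE 0.28) changed sign. Each of these SEs exceeds its shift, so the new signs are not settled. The endothelial list passed at -1.05 (SE 0.54). The covariate separates the genotypes by itself.

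Camera with an estimated correlation and fry left none of the 12 lists below the threshold, at the same mean changes: Notch targets 0.35, fibre -0.42, epithelium -0.27, S, G2 and M phase 0.69, G1 0.37, p53 0.37, FGF 0.24, capsule -0.34, heat shock 0.32, retina 1.47, macrophages 0.70 and glia 0.47. Adjusted p ran from 0.279 to 0.539 in camera with an estimated correlation and from 0.0593 to 0.180 in fry, which tests whether a list moves one way on balance. With the mean over all probe sets of a gene the hypoxia list passed (-0.16) and the glial list did not (0.34).

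Leaving out each array in turn gave 7 to 155 probe sets (6 to 124 higher, 1 to 40 lower, 7 to 155 at least 2-fold): 8 without wild type 1, 155 without wild type 2 (87 of the 211 among them), 49 without wild type 3, 12 without mutant 1, 7 without mutant 2 and 91 without mutant 3. Of the 12 lists 9 passed each time. The others ranged from -0.34 to -0.21 (epithelium), from 0.23 to 0.50 (p53) and from 0.16 to 0.33 (FGF), each losing its call in some, while the mesenchymal list (0.12 to 0.25) passed without wild type 2. The endothelial list ranged from -0.22 without wild type 3 to 0.25 without wild type 2, passing in both, so its direction rests on single arrays.

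Other probe sets went the other way in Thrsp (-0.049), Car8 (0.15), Fzd5 (-0.11) and Dnajb4 (-0.43). Over the whole chromosome of Notch2 in place of 20 Mb, the odds ratio of a gene passing was 2.02 (exact p = 0.0118).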

Other observations

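Of the tests in this part, those of the retinal covariate, of dilution and of other splits of the arrays were chosen only after the result was seen.

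Of the 166 genes that changed, 130 belonged to none of the lists. The genes named here were chosen after their values were seen. Rises were seen in the transcription factor genes Six6 (1.36, SE 0.21), Foxn4 (1.06, SE 0.16), Ptf1a (1.40, SE 0.22), Insm1 (1.26, SE 0.20) and Sox11 (1.52, SE 0.20), which are known from retinal or neural development, with limma adjusted p from 0.0298 to 0.0422. The growth factor gene Fgf15 rose by 1.93 (SE 0.20), Nyx, known from retinal bipolar cells, by 1.08 (SE 0.17) and Rrh, an opsin relative, by 1.65 (SE 0.23). The collagen genes Col2a1 (1.38, SE 0.20), Col11a1 (1.51, SE 0.21) and Col9a3 (1.51, SE 0.17), which are active in cartilage and the vitreous, and the fibrillin gene Fbn2 (0.99, SE 0.15) rose. Emilin3 (-1.37, SE 0.15), the protease gene Adamts18 (-1.40, SE 0.22) and the transcription factor gene Sall1 (-1.14, SE 0.16) fell, and so did the kinase gene Prkca by both probe sets that passed (-1.32 and -1.28). No group of these genes was tested.

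Of 25 retinal genes 8 rose in mutant lenses and of 37 S, G2 and M phase genes 1, with list means of 1.47 and 0.69 that lost their call with an estimated correlation (adjusted p = 0.279 and 0.338). Retinal tissue left on the mutant lenses is a candidate explanation: the retinal list's median change was 1.76, and photoreceptor (1.46, 5 genes), ganglion cell (1.88, 8 genes) and progenitor markers (1.28, 6 genes) all had medians above 0, with single genes from -0.16 (Rcvrn) and 0.33 (Sox2) up to the abundant neuronal genes Nefl (2.46, adjusted p = 0.140, though another of its probe sets passed at 2.55) and Stmn2 (2.47, adjusted p = 0.0544). With the retinal mean as a covariate the S, G2 and M phase shift went from 0.69 (SE 0.15) to 0.03 (0.034, SE 0.19). Dividing retinal progenitors would give such a drop, but the covariate itself separates the genotypes. The macrophage list went from 0.70 (SE 0.30) to -0.24 (SE 0.69), while the heat shock list stayed at 0.32 (SE 0.33). These errors are too wide to tell whether the drop is particular to dividing cells, so the drop does not decide. Against carried retinal tissue stands the protocol, in which surrounding tissue was dissected away. The centred values do not show how many of these genes the lens itself expresses. The list and class medians restate the rise itself, so they do not tell carried tissue from a change within lens cells. A change of lens cells toward a neural program through loss of Notch2 was not tested and stays open.

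Over all probe sets 2 of 29 lens fibre, 2 of 30 epithelium and 2 of 25 capsule genes fell and 2, 1 and 0 rose, and the list means of -0.42, -0.27 and -0.34 lost their call with an estimated correlation (adjusted p = 0.338, 0.539 and 0.279), the epithelium list also without wild type 1 (-0.21), wild type 2 (-0.26), mutant 2 (-0.23) or mutant 3 (-0.25). Dilution of lens RNA by RNA of another tissue would lower by about the same amount only the lens genes which that tissue does not express. The median over 84 measured members of these lists was -0.35, with quartiles at -0.73 and 0.05. Which of these members another tissue expresses was not examined, so changes this unequal do not decide on dilution. The 14 crystallins had a median of -0.03 (quartiles -0.15 and 0.04), 0.33 above the median of the 84, a smaller fall than even dilution would give. Yet their list mean was lower on every mutant array (-0.07, -0.10 and -0.03) than on any wild type array (0.04, -0.0049 and 0.04). Fitted beside genotype, its slope on the retinal list's mean was -0.079 (SE 0.013). The crystallins therefore do not decide either. Crystallin transcripts are so abundant that their probe sets may be saturated, which would hide a fall. Centred values hold no level to check this, so dilution, as the whole or a part of the fall, stays open. An effect of the Notch2 genotype on lens cells was not tested apart from dilution and stays open too.

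Of 21 measured heat shock and oxidative stress genes 3 rose over all probe sets, Hmox1, Hspb8 and Dnajb4. Hspb1 and Dnajb1, which the fibre list holds, rose too. Gstm1 fell by a probe set other than the one taken (-1.40, adjusted p = 0.0480). The heat shock list lost its call in camera with an estimated correlation (adjusted p = 0.338). Slower or rougher handling of the mutant lenses would raise immediate early genes, but the median of 12 such genes was 0.012. By the rule fixed beforehand, which used the median alone, this goes against handling. The quartiles were -0.11 and 0.30, so members went both ways and handling is not excluded. The retinal covariate left the list's shift at 0.32 (SE 0.33), too wide to separate it from 0. A stress response that follows from loss of Notch2 was not tested.

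Genes within 20 Mb of Notch2, where alleles of another strain linked to the targeted gene might differ between the genotypes, passed in 6 of 458 against 160 of 17570 elsewhere (odds ratio 1.44, 95% interval 0.52 to 3.24, Fisher's exact two-sided p = 0.321). The interval is too wide to decide, and the ratio was 0.79 within 5 Mb, 1.63 within 40 Mb and 2.02 over the whole chromosome.

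The real split of the arrays gave 211 probe sets and the highest of the other splits gave 1. Only 1 of the 10 splits of 6 arrays into 3 and 3, the real one, gave as many, and 10 splits are too few for a share under 0.05. The split that follows the hybridization controls gave 0 by limma, with 6138 at an unadjusted p under 0.05, more than the 5214 of the real split.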
